A study of Arabidopsis thaliana with 12 samples.

How the data were processed

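RNA sequencing was carried out on leaves of 12 Arabidopsis thaliana plants or plant pools of the Col-0 accession. Per the labels' protocols, plants stood for 1 h in chambers set to a relative humidity of 40 to 45% (low), 55 to 60% (moderate) or 95% (high), and each condition has 4 biological replicates. Total RNA was treated with DNase, and libraries were made with an Illumina TruSeq RNA kit and read as paired ends. The labels do not say whether a replicate is 1 plant or a pool, nor whether the 4 replicates of a condition stood in its chamber at the same time. P-values therefore rest on the spread between samples within a condition, pooled over the 3 conditions. A chamber, of which the labels name 3, cannot be separated from its humidity.

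Per the submitters' processing notes, the tools fastp, HISAT2 and RSEM were used with the TAIR10 build, and their versions, roles and settings are not given in the sources used here. The deposited values are TPM per gene, a length-scaled share of transcripts with a fixed total, although the table is titled as raw counts. They carry 2 decimals, and the 12 library columns sum to between 998920 and 999399, which is the fixed total of TPM and not that of counts. TPM keeps no sequencing depth, so the depth of each library is unknown, and no counting interval or detection floor is given. A change in a large group of transcripts moves all other TPM values, because the total is fixed. The authors' 3 columns of group means were not used. Strand handling and the treatment of reads shared between near-identical genes are not given in the sources used here, so values of close paralogs (such as members of the LHCB1, PIP2 and XTH families) are uncertain, as are those of overlapping or antisense genes.

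The table holds 32833 genes, of which 9128 were at 0 in all 12 libraries. Of the locus codes, 32548 matched the TAIR10.1 annotation used for names, gene length and GC content. A spreadsheet had turned 22 gene names into dates, and 856 names were blank. Locus codes were used throughout, with reference symbols in place of those names. Symbols fixed with the gene lists replace the table's own (XTH22 is listed there as TCH4, and RD29A as LTI78). Coordinates are not printed because the reference assembly is not the build of the table. A locus code gives the chromosome after the letters AT. No 2 libraries held the same values, and correlations between libraries of 1 condition lay between 0.960 and 0.985.

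Genes with a TPM of at least 1 in at least 4 libraries were kept, which left 17368 genes, 16647 of them protein-coding. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean for each of the 3 conditions, moderated variances with an intensity trend, robust moderation, 9 residual degrees of freedom and Benjamini-Hochberg adjustment over the tested genes. The threshold was an adjusted p of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes of low TPM. A quasi-likelihood test of counts had been fixed before the data were examined. It needs counts, so the stated substitute, limma with an intensity trend, was used. The comparisons were high against moderate, low against moderate and high against low humidity. A further contrast set moderate humidity against the mean of the other conditions.

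On simulated data for high against moderate humidity, with 200 of the 17368 genes changed, the test recovered 46.0% of genes changed 1.5-fold, 81.5% of those changed 2-fold and 93.0% of those changed 4-fold. Of the calls, 4.18% were false. The simulation gave each gene independent normal errors and left out shifts common to a library, so these rates need not hold for the real calls.

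Before the data were examined, 32 gene lists with 411 members were fixed from general knowledge. Of these members 331 were tested, and 30 lists had at least 3 tested members. Lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over the 30 lists. Camera compares a list with all other tested genes. The alternatives were an estimated correlation and limma's fry, which asks whether a list's genes move one way on balance. None of the list calls held with an estimated correlation.

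Genes named in the text follow a rule fixed before the data were examined. For each comparison it takes, among genes past the threshold with a mean log2 value of at least 1 and no overlap between the 4 and 4 libraries, the 12 with the largest rise and the 12 with the largest fall. It adds up to 4 members of each list with the smallest adjusted p, and all members of the lists of abscisic acid (ABA) biosynthesis and of ABA catabolism. Genes named outside this rule were chosen after their values were seen. At high against moderate humidity these are XTH24, PYL6, PYL7, PIP2;3, TOC1, PIF5, LHB1B2 and the EXPA genes of the cell wall list, and at high against low humidity AFP3 and HSFA2.

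TPM was used as deposited for the main results. Alternatives chosen after the data were seen were median-of-ratios scaling of TPM, a pseudocount of 0.1, removal of each library's smooth trend on gene length and GC content, and median-of-ratios scaling without low humidity replicate 1. Length and GC content were known for 17300 of the tested genes (99.6%). Alternatives fixed beforehand were other filters, a fit of only the compared conditions, a replicate block, a fold minimum and leaving out each library in turn. Count models were not run. Other splits of the libraries, with at most 100 per result, were refitted in the same way.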

Results

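Leaf transcriptomes of Arabidopsis Col-0 were measured after 1 h at low (40 to 45%), moderate (55 to 60%) or high (95%) relative humidity, with 4 libraries per condition. Plants had been raised near the moderate setting, so the moderate libraries serve as the control. Each library holds TPM values of fixed total, and the sequencing depth is unknown. Between 20691 and 20967 genes were above 0 per library. The first principal component of log2(TPM + 1) took 48.1% of the variance and set the 4 high humidity libraries (scores 46.4 to 65.5) apart from the 8 others (scores -32.9 to -19.7).

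The libraries also differed in how much of their total came from photosynthetic transcripts. Genes described as photosystem, chlorophyll or Rubisco genes (91 genes) took 23.6% ± 0.109 of TPM at moderate humidity (SD, n = 4), 27.1% ± 0.784 at high humidity and 29.0% ± 2.50 at low humidity. Low humidity replicate 1 had 25.3%, against 29.5 to 31.0% in the other low humidity libraries. Plastid-encoded genes took 0.185% ± 0.0175 at moderate, 0.300% ± 0.0298 at high and 0.304% ± 0.0575 at low humidity. Of 4 root marker genes only SCR was tested (39.6 ± 5.70 TPM at moderate humidity), and PYK10, CASP1 and WER stayed at or under 0.51 TPM in every library. Of 3 flower marker genes only AG was tested, at no more than 3.5 TPM in any library.

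**Figure D1:**
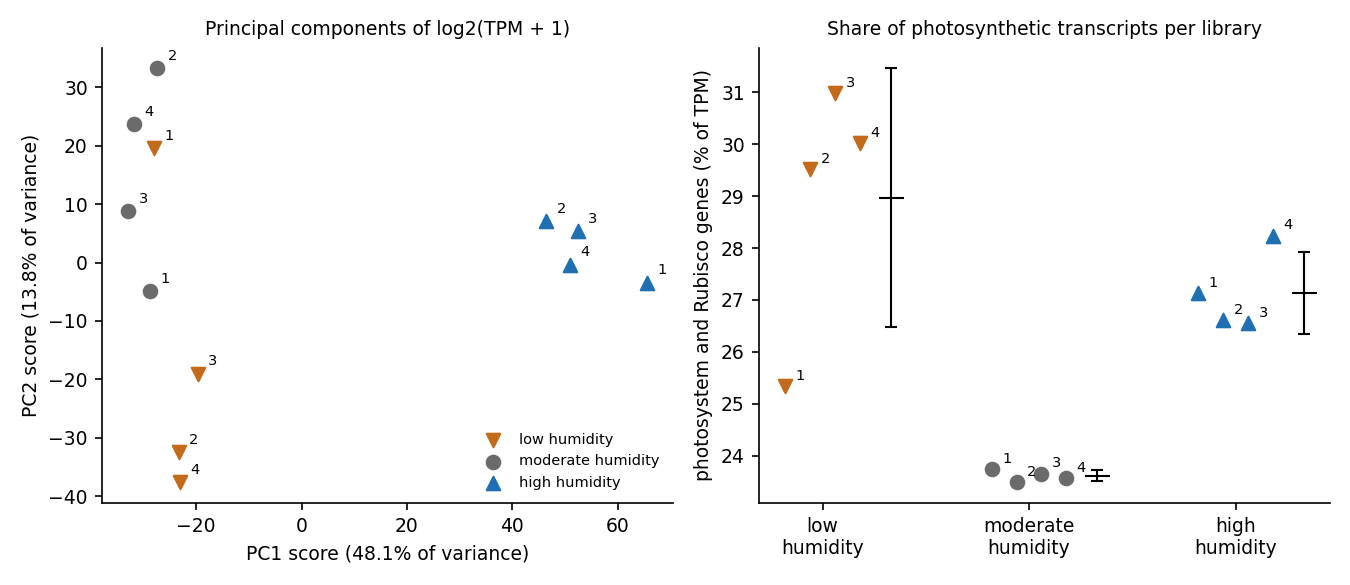
Left, scores of the 12 libraries on the first 2 principal components of log2(TPM + 1), with the replicate number beside each point. Right, percent of TPM from photosystem, chlorophyll and Rubisco genes per library, with mean and SD (n = 4) per condition; low humidity replicate 1 lies at 25.3%, and the 4 moderate libraries lie between 23.5 and 23.7%.

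High against moderate humidity asks what 1 h of nearly saturated air did to leaf transcripts. At high humidity 10 of 15 genes of a cell wall list, 4 of 8 touch genes and 5 of 9 ABA receptor genes rose, while 16 of 21 genes responsive to ABA, the hormone of water deficit, fell. XTH22 (AT5G57560), a touch-inducible xyloglucan endotransglucosylase/hydrolase, went from 7.78 ± 7.33 to 815 ± 193 TPM (SD, n = 4). P5CS1 (AT2G39800), an enzyme of proline synthesis, went from 309 ± 101 to 21.4 ± 3.14 TPM. PYL4 (AT2G38310), an ABA receptor, went from 12.2 ± 2.70 to 244 ± 44.4 TPM. All 3 changes exceeded the spread between replicates, with limma adjusted p of 1.5e-05, 5.4e-08 and 1.5e-09.

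In total, 1981 genes were higher and 5938 lower at high than at moderate humidity at an adjusted p of 0.05, and 752 of the former and 593 of the latter changed at least 2-fold. The median gene had a log2 fold change of -0.22. Median-of-ratios scaling moved this median to -0.02 and gave 3204 genes higher and 2608 lower, so that the share of lower genes went from 75.0 to 44.9%. All 1981 higher genes and 2608 of the lower ones were called in the same direction under both scalings. The scaling raised the fold changes of this comparison, so the higher genes could hardly lose their calls by it. The 4 and 4 libraries did not overlap in 45.8% of the tested genes, against 2.86% expected by chance for a single gene, a value that ignores shifts common to a library.

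**Figure D2:**
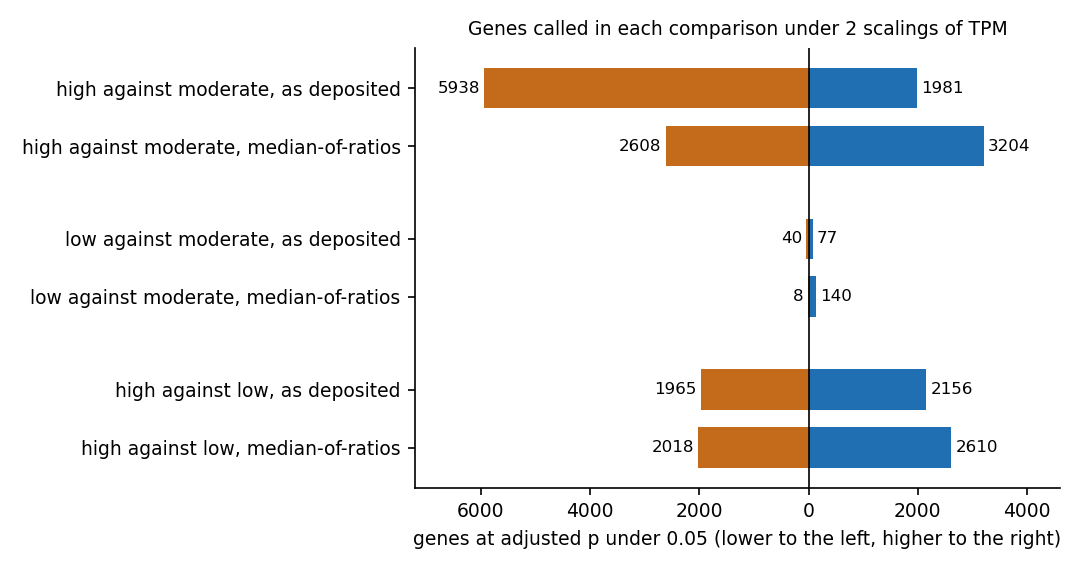
Number of genes at an adjusted p of 0.05 in each comparison (limma), with genes lower in the first-named condition to the left and higher to the right, for TPM as deposited and after median-of-ratios scaling. For high against moderate humidity the scaling moved the lower genes from 5938 to 2608 and the higher genes from 1981 to 3204.

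Genes with the largest rises included members of the EXORDIUM, XTH and expansin-like families. PHI-1 (AT1G35140), of the EXORDIUM family, rose by 8.20 on the log2 scale (SE 0.28, adjusted p = 1.8e-09), from 1.08 ± 1.01 to 572 ± 116 TPM. EXO (AT4G08950), the family's founding member, rose by 6.08 (SE 0.33), and EXL3 (AT5G51550) and EXL5 (AT2G17230) rose by 5.07 and 4.80. The expansin-like gene EXLA1 (AT3G45970) rose by 6.71 (SE 0.48), XTR6 (AT4G25810) by 5.32, XTH16 (AT3G23730) by 4.89 and the arabinogalactan protein gene AGP7 (AT5G65390) by 4.70. AT1G72416 and AT4G16563 rose by 5.33 and 5.02. XTH33 (AT1G10550) was listed at 0 in all 4 moderate libraries and reached 79.7 ± 16.8 TPM at high humidity. The largest falls included XTH31 (AT3G44990, log2 fold change -4.33, SE 0.31), P5CS1 (-3.74, SE 0.20), the expansin gene EXPA16 (AT3G55500, -3.71, SE 0.34) and GolS2 (AT1G56600, -3.38, SE 0.53), a galactinol synthase induced by drought. The transcription factor gene ERF53 (AT2G20880, -3.15), PRE1 (AT5G39860, -3.13), CYP71B26 (AT3G26290, -3.02) and the root growth factor gene RGF9 (AT5G64770, -3.01) fell as well.

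The list of cell wall expansion genes was called upward (camera adjusted p = 6.4e-05; adjusted p = 0.204 with an estimated correlation), with 10 of 15 tested members risen and 5 fallen under both scalings. Its families moved apart. All 9 XTH genes of the list rose, among them XTH4 (AT2G06850, from 176 ± 12.0 to 1115 ± 164 TPM), XTH24 (AT4G30270, log2 fold change 3.54, SE 0.26) and XTH9 (AT4G03210, 2.24, SE 0.17). XTH31, which is not in the list, fell. Of 6 EXPA genes in the list, which encode expansins, 5 fell (EXPA1, EXPA4, EXPA8, EXPA10 and EXPA11, by 0.85 to 1.58) and EXPA5 (AT3G29030) rose by 0.39. Of 8 touch and calmodulin-like genes, 4 rose and none fell (camera adjusted p = 0.0011; adjusted p = 0.471 with an estimated correlation). These were XTH22, the calmodulin-like calcium sensor genes CML24 (AT5G37770, 2.19, SE 0.14), CML23 (AT1G66400, 0.77, SE 0.20) and CML12 (AT2G41100, 1.68, SE 0.40). Adjusted over the list alone the counts of both lists were the same.

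**Figure D3:**
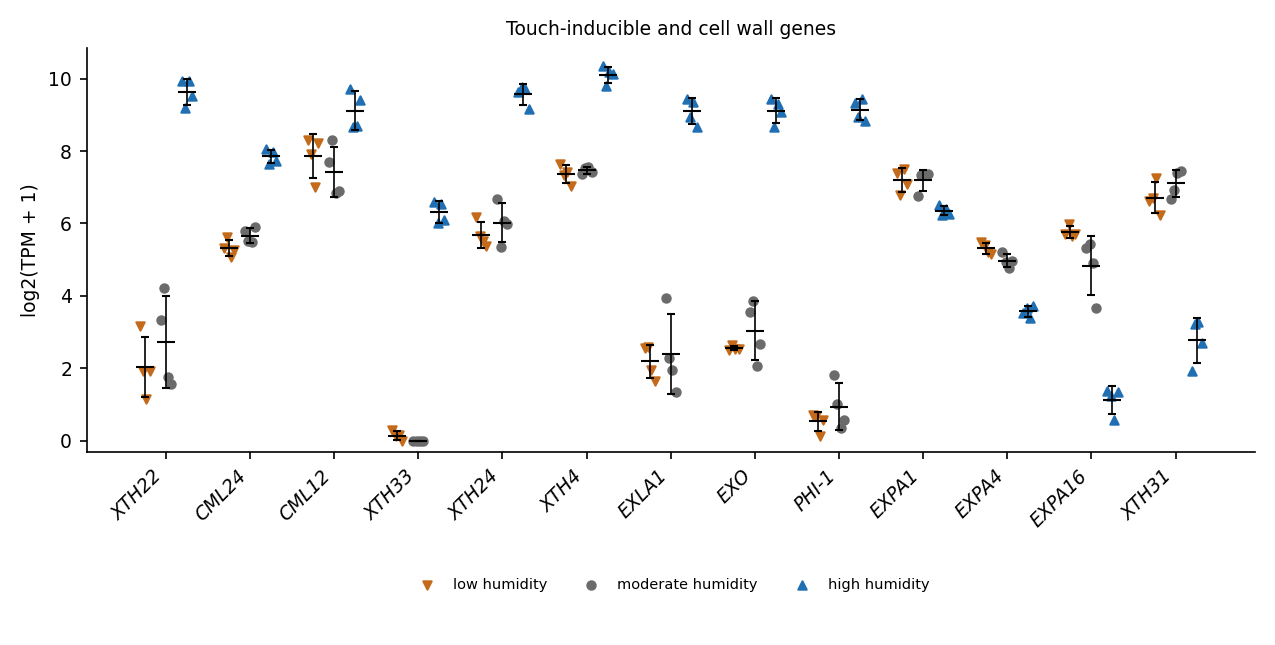
Log2(TPM + 1) of touch-inducible and cell wall genes in each library at low, moderate and high humidity, with mean and SD (n = 4) in black. The 4 high humidity libraries lie above all others for XTH22, whose mean was 815 TPM there, and below all others for XTH31, whose mean was 6.33 TPM.

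ABA-related lists moved in both directions. Of 21 ABA-responsive genes, 16 fell and none rose (camera adjusted p = 1.7e-04; adjusted p = 0.612 with an estimated correlation); adjusted over the list alone 17 fell, and 14 fell after median-of-ratios scaling. HB12 (AT3G61890, log2 fold change -2.26, SE 0.19) and HB7 (AT2G46680, -1.88, SE 0.18), 2 ABA-induced homeodomain genes, fell, as did the phosphatase gene ABI1 (AT4G26080, -2.01, SE 0.14) and the transcription factor gene ABF3 (AT4G34000, -1.23, SE 0.13). Receptor genes went the other way. Of 9 ABA receptor genes, 5 rose and 1 fell (camera adjusted p = 3.9e-05; adjusted p = 0.275 with an estimated correlation). PYL5 (AT5G05440) rose by 4.67 (SE 0.31), PYL4 by 4.22 (SE 0.16), PYL6 (AT2G40330) by 1.61 and PYR1 (AT4G17870) by 1.45. Adjusted over the list alone 5 receptor genes rose and 1 fell. PYL7 (AT4G01026) fell by 0.83, with an adjusted p of 0.077 after median-of-ratios scaling.

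All 6 tested ABA biosynthesis genes fell. The list was not called as deposited (camera adjusted p = 0.058; adjusted p = 0.418 with an estimated correlation) and was called downward after median-of-ratios scaling (camera adjusted p = 0.037), where 3 members fell. ABA1 (AT5G67030), ABA3 (AT1G16540) and AAO3 (AT2G27150) fell under both scalings, by 0.60, 0.49 and 0.71 as deposited. NCED3 (AT3G14440), which encodes the dioxygenase that limits stress-induced ABA synthesis, went from 2.24 ± 0.872 to 0.89 ± 0.347 TPM (log2 fold change -0.75, adjusted p = 0.034). After median-of-ratios scaling its adjusted p was 0.119, and those of ABA2 (AT1G52340) and ABA4 (AT1G67080) were 0.234 and 0.132, each the highest over 12 alternative settings, whose lowest adjusted p were 0.0090, 0.0014 and 0.014. Of 5 tested genes of ABA catabolism and conjugation, 2 rose and 1 fell (camera adjusted p = 0.069). CYP707A1 (AT4G19230), an ABA 8'-hydroxylase gene, rose by 1.47 (SE 0.19, adjusted p = 8.6e-05), from 1.04 ± 0.553 to 4.54 ± 0.855 TPM, and the glucosyltransferase gene UGT71C5 (AT1G07240) rose by 0.56. CYP707A4 (AT3G19270) fell by 0.57, with an adjusted p of 0.074 after scaling, the highest of its alternatives. CYP707A3 (AT5G45340) had a log2 fold change of 0.82 (adjusted p = 0.094; 0.048 after scaling and up to 0.233 in other alternatives), and CYP707A2 (AT2G29090) one of -0.21 (adjusted p = 0.344).

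**Figure D4:**
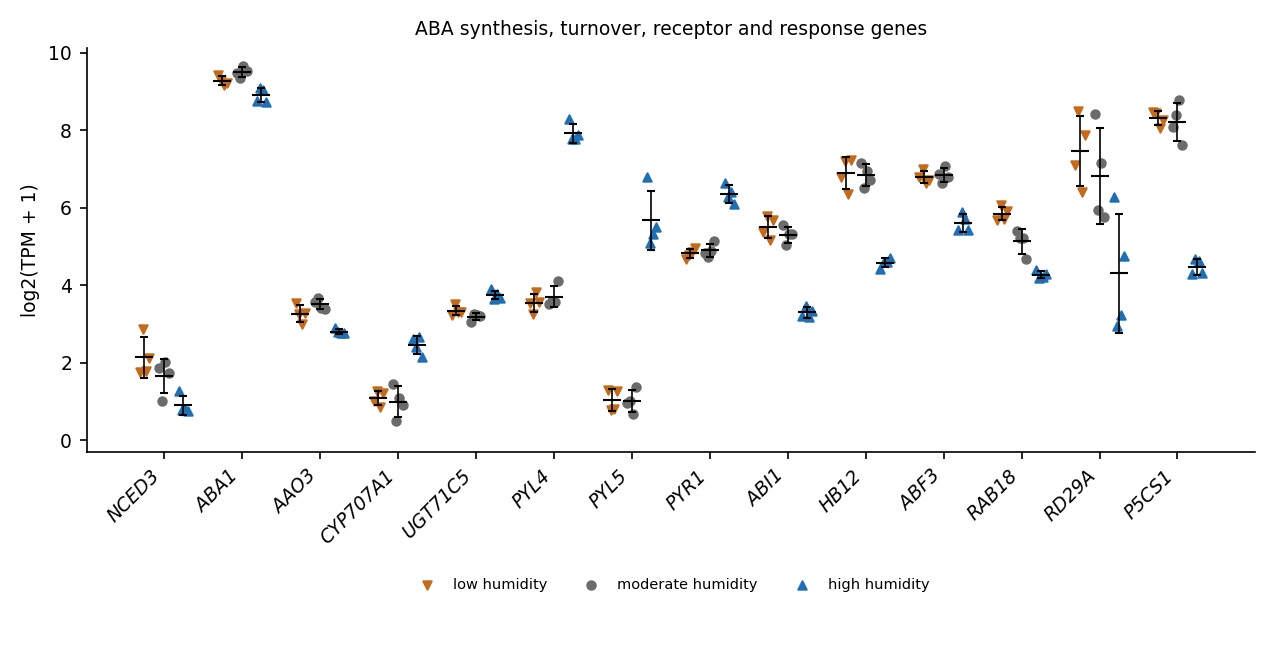
Log2(TPM + 1) of genes of ABA synthesis, turnover, perception and response in each library at low, moderate and high humidity, with mean and SD (n = 4) in black. PYL4 averaged 244 TPM at high humidity and 12.2 TPM at moderate humidity, and P5CS1 averaged 21.4 and 309 TPM.

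Cytokinin response genes fell at high humidity, 7 of 10 tested and none upward (camera adjusted p = 0.020; adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone 8 fell. They included 6 of the 8 tested ARR genes, early cytokinin response regulators, such as ARR15 (AT1G74890, -1.99, SE 0.23) and ARR8 (AT2G41310, -1.61, SE 0.16). Photosynthesis genes rose in 7 of 14 cases and fell in none (camera adjusted p = 0.0011; adjusted p = 0.612 with an estimated correlation), by small amounts such as 0.53 (SE 0.09) for LHCB4.1 (AT5G01530) and 0.45 (SE 0.11) for RBCS3B (AT5G38410). Adjusted over the list alone 7 rose as well. The larger share of photosynthetic transcripts in the high humidity libraries sums genes of the same kind, so it is no separate evidence of this rise. With the length and GC trend removed, the photosynthesis list was no longer called and LHCB4.1 had a log2 fold change of 0.18 (adjusted p = 0.055, with 3.9e-04 as the lowest of its alternatives).

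In other lists members changed without a call of the list. Of 5 calcium channel and CAMTA genes 1 rose, CNGC2 (AT5G15410, 1.09, SE 0.12), and 3 fell, among them CNGC4 (AT5G54250, -0.75, SE 0.11), while after median-of-ratios scaling 2 rose and 1 fell (camera adjusted p = 0.901). Of 13 guard cell genes 3 rose and 3 fell under both scalings, with the anion channel gene SLAH3 (AT5G24030) rising by 3.32 (SE 0.20) (camera adjusted p = 0.633). Of 11 CBF cold and dehydration genes 1 rose, ERD15 (AT2G41430, 2.18, SE 0.33), and 5 fell, of which P5CS1 and GolS2 also fell after scaling (camera adjusted p = 0.637). In the aquaporin list, 5 genes rose and 4 fell of 17 tested (camera adjusted p = 0.058). PIP2;7 (AT4G35100) and TIP2;1 (AT3G16240) both rose by 1.14, while PIP2;3 (AT2G37180) fell by 1.73 and PIP2;2 (AT2G37170) by 1.35. Of 8 unfolded protein response genes 1 rose as deposited (camera adjusted p = 0.078; adjusted p = 0.797 with an estimated correlation), and 6 rose after median-of-ratios scaling, where the list was called upward (camera adjusted p = 0.018). No list call held with an estimated correlation. The lowest adjusted p was then 0.204, and limma's fry called 14 of the 30 lists against 6 by camera. Camera called 14 lists without moderate humidity replicate 2, 10 without high humidity replicate 2 and 15 without high humidity replicate 3.

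Low against moderate humidity asks what 1 h of drier air did. Of 14 photosynthesis genes 3 rose, as did the light-harvesting gene LHB1B2 and the ABA-induced dehydrin gene RAB18. LHB1B2 (AT2G34420), a light-harvesting chlorophyll-binding protein gene, went from 4252 ± 643 to 9778 ± 1371 TPM (log2 fold change 1.2, SE 0.12, limma adjusted p = 0.0022). RAB18 (AT5G66400) went from 34.6 ± 7.2 to 56.7 ± 6.95 TPM (0.71, adjusted p = 0.039). The low humidity libraries also had a larger photosynthetic share than the moderate ones, and low humidity replicate 1 had the smallest such share among them. This share sums genes of the same kind, so it is no separate evidence of the rise of photosynthesis and light-harvesting genes.

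At low humidity 77 genes were higher and 40 lower, and 5077 genes had an unadjusted p under 0.05. The median log2 fold change was -0.18 as deposited and -0.01 after median-of-ratios scaling, which gave 140 genes higher and 8 lower. Without low humidity replicate 1 the counts were 388 and 5217 as deposited, and 623 and 99 after scaling. Without low humidity replicates 2, 3 or 4 they were 18 and 2, 20 and 1, and 22 and 1, and without moderate humidity replicates 1, 3 or 4 they were 41 and 18, 34 and 1, and 47 and 9. The libraries of the 2 conditions did not overlap in 10.5% of the tested genes, against 2.86% expected by chance for a single gene. Genes of a library can shift together, so the share over all genes can exceed this value without a response to humidity.

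The largest rises included CWLP (AT3G22120), a cell-wall-plasma-membrane linker protein gene (log2 fold change 1.61, SE 0.25), Tic20-II (AT2G47840, 1.52, SE 0.30) of plastid protein import, the ubiquitin ligase gene RHA3A (AT2G17450, 1.23), the arabinogalactan protein gene AGP4 (AT5G10430, 1.22, SE 0.16), ERF8 (AT1G53170, 1.19), the long non-coding RNA gene AT1G09927 (1.12) and LHB1B1 (AT2G34430, 1.09). The plastid loci ATCG00950 and ATCG01180 had identical values in every library and rose by 1.15. The long non-coding RNA gene AT4G36808 went from 31.4 ± 13.1 to 5.43 ± 2.82 TPM (log2 fold change -2.34, SE 0.36, adjusted p = 0.018), the non-coding RNA gene AT2G45245 fell by 1.37 and AT1G72800 fell by 0.91. SPL2 (AT5G43270), a squamosa-promoter binding protein gene, fell by 0.65 (adjusted p = 0.048), but its adjusted p was 0.124 after median-of-ratios scaling (0.0080 to 0.156 over its alternatives).

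Camera called 9 lists upward at low humidity, mostly on members that did not pass the test singly. Of 14 photosynthesis genes 3 rose and none fell, and 6 rose when adjusted over the list alone (camera adjusted p = 3.2e-11; adjusted p = 0.302 with an estimated correlation). These were LHCB2.2 (AT2G05070, 0.59, SE 0.09), LHCB4.1 (0.59, SE 0.09) and PSAD1 (AT4G02770, 0.48, SE 0.08). With the length and GC trend removed 1 of the 14 rose. Of 17 aquaporin genes 1 rose, TIP1;2 (AT3G26520, 0.66, adjusted p = 0.045; 0.051 after scaling and 0.0023 to 0.165 over its alternatives), and 6 rose when adjusted over the list alone (camera adjusted p = 1.2e-11; adjusted p = 0.302 with an estimated correlation). RAB18 was the 1 ABA-responsive gene of 21 that rose (camera adjusted p = 3.3e-07; adjusted p = 0.479 with an estimated correlation). No member of the lists for CBF cold and dehydration genes, salicylic acid, light response and flavonoids, cuticle and wax, vascular tissue or cell wall expansion passed the test over all genes, and their camera adjusted p of 7.6e-05, 5.9e-04, 0.0021, 5.2e-04, 0.0081 and 0.021 became adjusted p of 0.479, 0.599, 0.479, 0.479, 0.302 and 0.479 with an estimated correlation. Adjusted over the list alone 1 gene of the salicylic acid, 1 of the cell wall and 1 of the vascular list rose, as did 2 cuticle genes, while 1 cuticle gene fell. The cell wall list was called upward although its median log2 fold change was -0.04, because camera sets a list against the other genes. Its call was lost after median-of-ratios scaling and without low humidity replicate 3 or moderate humidity replicate 2 (camera adjusted p up to 0.096 without 1 library). The light response call was lost without moderate humidity replicate 2 (0.105) and the cuticle call without moderate humidity replicate 4 (0.078), and the light response and vascular calls were lost with the length and GC trend removed.

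The ABA genes that changed at high humidity gave no call at low humidity apart from RAB18. NCED3 was at 3.63 ± 1.87 TPM against 2.24 ± 0.872 (log2 fold change 0.49, adjusted p = 0.228), CYP707A1 had a log2 fold change of 0.10 (adjusted p = 0.737) and PYL4 one of -0.16 (adjusted p = 0.514), which turned to 0.02 after median-of-ratios scaling. Fry called none of the 30 lists.

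High against low humidity compares the outer settings, both away from the control. At high humidity 9 of 15 wall genes were higher and 5 lower, 4 of 8 touch genes, 5 of 9 ABA receptor genes and 5 of 9 heat shock genes were higher, and 18 of 21 ABA-responsive genes were lower. PHI-1 was at 572 ± 116 TPM at high and 0.468 ± 0.253 TPM at low humidity (log2 fold change 8.60, SE 0.28, limma adjusted p = 1.1e-09). RAB18 was at 18.3 ± 1.18 and 56.7 ± 6.95 TPM (-1.58, SE 0.14, adjusted p = 2.5e-06).

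There were 2156 genes higher and 1965 lower at high than at low humidity, 821 and 422 of them at least 2-fold. After median-of-ratios scaling the counts were 2610 and 2018, and 2143 higher and 1805 lower genes were called under both scalings. The libraries did not overlap in 26.3% of the tested genes, against 2.86% expected by chance for a single gene, a value that ignores shifts common to a library. The largest rises again included XTH22 (log2 fold change 7.60, SE 0.60), EXLA1 (6.90), EXO (6.56), XTH16 (5.54) and the purine permease gene PUP18 (AT1G57990, 4.82). The largest falls included EXPA16 (-4.64, SE 0.34), ERF53 (-4.23, SE 0.46), XTH31 (-3.93), P5CS1 (-3.83), PUB19 (AT1G60190, -3.23), a ubiquitin ligase gene of drought signalling, RD29A (AT5G52310, -3.17, SE 0.85) and the heat shock factor gene HSFC1 (AT3G24520, -3.16).

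Camera called 10 lists in this comparison. Of 21 ABA-responsive genes 18 fell (camera adjusted p = 5.0e-11; adjusted p = 0.379 with an estimated correlation), among them ABI1 (-2.20), HB12 (-2.32) and AFP3 (AT3G29575, -2.93). Of 6 ABA biosynthesis genes 3 fell, NCED3 (-1.23, SE 0.26), ABA1 (-0.37) and AAO3 (-0.47) (camera adjusted p = 0.034; adjusted p = 0.379 with an estimated correlation). Of 9 ABA receptor genes 5 rose and 1 fell (camera adjusted p = 6.4e-04; adjusted p = 0.379 with an estimated correlation). Touch genes rose in 4 of 8 cases (camera adjusted p = 0.0028; adjusted p = 0.379 with an estimated correlation). In the cell wall list 9 of 15 rose, all of them XTH genes, and 5 fell, all of them EXPA genes (camera adjusted p = 0.0048; adjusted p = 0.379 with an estimated correlation). Cytokinin response genes fell in 6 of 10 cases (camera adjusted p = 0.0048; adjusted p = 0.453 with an estimated correlation).

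Of 9 heat shock genes 5 rose relative to low humidity (camera adjusted p = 0.032; adjusted p = 0.379 with an estimated correlation). These were the chaperone genes HSP70-4 (AT3G12580, 1.15, SE 0.21), HSP101 (AT1G74310, 0.78) and HSP90-1 (AT5G52640, 1.1), and the heat shock factor genes HSFA7A (AT3G51910, 1.34, SE 0.23) and HSFA2 (AT2G26150, 1.00). Of 8 unfolded protein response genes 2 rose, and 4 after scaling, with BZIP60 (AT1G42990, 0.64) and CNX1 (AT5G61790, 0.44) called as deposited (camera adjusted p = 0.034; adjusted p = 0.764 with an estimated correlation). Light response and flavonoid genes fell in 6 of 8 cases, and in 3 after scaling (camera adjusted p = 0.014; adjusted p = 0.618 with an estimated correlation), with CHI (AT3G55120, chalcone isomerase) at -1.72 and FLS1 (AT5G08640, flavonol synthase) at -1.51. Of 11 CBF cold and dehydration genes 4 fell and ERD15 rose by 1.73 (camera adjusted p = 0.017; adjusted p = 0.659 with an estimated correlation). Adjusted over the list alone 4 ABA biosynthesis genes and 8 CBF genes fell and 5 touch genes rose, and the other counts were the same. No list call held with an estimated correlation. Calls of ABA biosynthesis, CBF, heat shock and unfolded protein response genes were each lost when 1 to 3 single libraries were left out, with adjusted p up to 0.052, 0.067, 0.070 and 0.077.

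The contrast of moderate humidity with the mean of both others also takes in genes changed at high humidity alone, so its calls do not measure a departure from the order of humidity. Here 6353 genes were called, 1198 of them higher and 5155 lower in the mean of the outer conditions, and rearranging the low and moderate libraries with high humidity kept in place still called at least 902. Median-of-ratios scaling turned the balance, with 2060 higher and 1140 lower. Light-harvesting genes were among those higher in both outer conditions: LHB1B2 rose by 0.71 at high and by 1.2 at low humidity, LHCB2.2 by 0.36 and 0.59, and LHCB4.1 by 0.53 and 0.59.

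Calls shared by high and low humidity, each against moderate, numbered 86 in the same direction, 61 upward and 25 downward, and 10 in opposite directions. Independent lists of these sizes would share 22.5 genes in the same direction, and simulated unchanged groups shared 0. The first value ignores that both comparisons use the same moderate libraries. The simulation gave each gene independent errors and left out shifts common to a library. Neither value is therefore a chance level for the 86. Across genes, which are not independent replicates, the log2 fold changes of the comparisons correlated with r = 0.297 and a covariance of 0.0538, against 0.507 and 0.0261 for unchanged groups set against the same controls. With the moderate libraries split 2 and 2, the mean was r = 0.133 with a covariance of 0.0283 over 6 splits. Without low humidity replicate 1 the shared calls numbered 3725, and after median-of-ratios scaling of all libraries 124. Without low humidity replicates 2, 3 or 4 they numbered 17, 19 and 20, without moderate humidity replicates 1, 3 or 4 they numbered 48, 29 and 45, and without high humidity replicates 3 or 4 they numbered 57 and 56.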

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

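Apart from the counts of splits, tests of explanations here were chosen after the result was seen. In 117 sets of 4 libraries, drawn from library measures and list means, 9 had 1 library farther from its nearest neighbour than Dixon's 95% limit allows. Chance alone gives about 1 in 20. Among 249 named genes, 50 of 745 sets of 4 did so (6.71%), and 16 of these 50 were in low humidity replicate 1.

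Low humidity replicate 1 had a median-of-ratios factor of 1.11, against 0.908 to 0.928 in the other low humidity libraries. In high humidity replicate 1, the mean log2 value of ABA-responsive genes was 3.88, against 3.43 to 3.48 in the other high humidity libraries, and that of dividing cell markers was 1.76, against 2.01 to 2.07. In moderate humidity replicate 4, the mean log2 value of ABA receptor genes was 3.69, against 3.42 to 3.44, and that of auxin-responsive genes was 3.35, against 3.01 to 3.04. The oxidative stress mean of high humidity replicate 3 was 5.12, against 5.46 to 5.50, and the photosynthesis mean of high humidity replicate 4 was 12.82, against 12.75 to 12.76. The 100 most abundant genes took 36.3% of TPM in moderate humidity replicate 2, against 36.9% in the others. The TPM total of high humidity replicate 1 was 998920, against 999111 to 999141.

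The rise of photosynthesis genes at low humidity, with low humidity replicate 1 in between, was weighed against technical explanations. Of all 35 splits of the 8 libraries, 2 called at least the 117 genes of the real split. The other was the exchange of low humidity replicate 1 with moderate humidity replicate 1, which called 4105, so on the deposited scale a chance arrangement of the libraries is not excluded and the libraries hold a structure that the labels do not describe; after median-of-ratios scaling the exchange called 146 (106 higher, 40 lower) and the real split 148 (140 higher, 8 lower). The photosystem share of moderate humidity replicate 1, 23.7%, lay with the other moderate libraries, which argues against a swap of these 2 samples. Its share of the 100 most abundant genes (36.9%) and plastid-encoded share (0.181%) did so too. Its second principal component score of -4.91 lay between the other moderate libraries (8.8 to 33.2) and low humidity replicates 2 to 4 (-37.6 to -19.0). It correlated at 0.976 with low humidity replicates 2 and 4, and at 0.968 to 0.980 with the other moderate libraries. A swap is therefore not excluded. A moderate sample under a low humidity label cannot be told apart from a low humidity sample that responded less, because the measures of low humidity replicate 1 disagree: its photosystem share of 25.3% (moderate 23.5 to 23.7%, other low 29.5 to 31.0%), share of the 100 most abundant genes of 38.2% (36.3 to 36.9%, 42.6 to 44.5%) and plastid-encoded share of 0.219% (0.172 to 0.210%, 0.320 to 0.345%) lay between both groups, while its median-of-ratios factor of 1.11 (moderate 1.06 to 1.16), rank correlation with gene length of 0.0987 (moderate -0.00332 to 0.135, other low -0.127 to -0.0571) and second principal component score of 19.6 (moderate -4.91 to 33.2, other low -37.6 to -19.0) lay within the moderate range, and its correlations were 0.968 to 0.981 with the moderate and 0.960 to 0.971 with the other low humidity libraries. Each library was also placed on an axis from moderate (0) to low humidity (1), built from 1000 genes without that library. Low humidity replicates 1 to 4 lay at 0.43, 0.91, 0.59 and 0.49 on average. Moderate humidity replicates 1 to 4 lay at 0.46, 0.50, 0.27 and 0.25. Moderate humidity replicates 1 and 2 thus lay nearer the low end than low humidity replicate 1, so the 2 conditions overlapped on this axis. A length or GC trend between libraries stays open for the rise. Removing it took the mean log2 fold change of the photosynthesis list from 0.191 (SE 0.0616 over 14 members) to 0.061 (SE 0.0541). The latter is within 2 SE of 0, the outcome taken to go with such a trend, but it does not decide. Each library kept its own mean, so 0 is not the level of an unchanged gene on this scale. The SE is taken over genes that moved together (estimated correlation 0.48) and not over libraries. Members called higher went from 3 to 1. The list was still called (camera adjusted p = 5.2e-04), but camera sets it against the other genes, and the median of all tested genes was then -0.17. A response to drier air stays open as well.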

How the results depend on the processing

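Median-of-ratios scaling, the pseudocount of 0.1, the removed length and GC trend, and the scaling without low humidity replicate 1 were chosen after the data were seen. TPM gives no depth, so what depth limits cannot be stated, and the 2 count models that had been planned were not run because they need counts. Scaling to total counts needs counts too and was not run. Unless a construction is named, the cause was not tested. Median-of-ratios scaling, which centres the median gene, gave 3204 genes higher and 2608 lower for high against moderate humidity, 140 and 8 for low against moderate, and 3200 with moderate humidity apart. Without low humidity replicate 1 that scaling gave 623 higher and 99 lower for low against moderate humidity, 3750 with moderate humidity apart and 512 shared calls. Without the filter, low against moderate humidity gave 46 higher and 13 lower, and 51 calls were shared. With only the 2 compared conditions in the fit it gave 38 and 6. A minimum log2 change of 1, which removes genes by construction, left 752 higher and 593 lower for high against moderate, 16 and 3 for low against moderate, and 821 and 422 for high against low humidity. With the length and GC trend removed, low against moderate humidity gave 37 and 20, and 44 calls were shared. With an estimated correlation 0 lists were called in each comparison, and fry called 14 for high against moderate and 0 for low against moderate humidity.

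Replicate numbers do not pair the libraries. Of 12 pairs of equal number, 4 had deviations that correlated above 0.1 (range -0.32 to 0.24), and 3 of the 12 libraries correlated best with their own number. A replicate block gave 1900 higher and 5162 lower for high against moderate, 2060 and 1654 for high against low, 25 and 1 for low against moderate humidity, 4983 with moderate humidity apart and 22 shared calls. For low against moderate humidity the named genes then not called included RAB18, CWLP, Tic20-II and AT4G36808 (adjusted p of 0.103, 0.0777, 0.123 and 0.0744). LHB1B1, AT2G45245 and SPL2 were among them too (0.117, 0.0864 and 0.103). LHB1B2 was still called (0.0190).

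Leaving out 1 library at a time gave 1658 to 1906 higher and 4728 to 5691 lower for high against moderate, and 1798 to 2593 higher and 1426 to 1908 lower for high against low humidity. For low against moderate it gave 18 (without low humidity replicate 2) to 388 higher and 1 (without low humidity replicate 3) to 5217 lower, both maxima without low humidity replicate 1. The contrast of moderate with both others gave 4346 to 8349 genes, and shared calls ranged from 17 (without low humidity replicate 2) to 3725 (without low humidity replicate 1). Lists called ranged from 6 to 15 for high against moderate (15 without high humidity replicate 3), 9 to 11 for low against moderate and 8 to 11 for high against low humidity. Of 243 named results past the threshold, 211 stayed past it in the same direction under median-of-ratios scaling, 219 with the block, 240 with the pseudocount of 0.1, 227 with the trend removed and 194 in every fit with 1 library left out. None turned direction. Among uncalled fold changes of the ABA biosynthesis and catabolism genes, those that did were ABA2 (8.7e-05) and ABA3 (0.0032) for low against moderate humidity after scaling, ABA4 for high against low (-0.153 without low humidity replicate 3 to 0.0506 without low humidity replicate 1), CYP707A1 for low against moderate (-0.0649 without moderate humidity replicate 2 to 0.256 without moderate humidity replicate 1) and CYP707A2 for high against low (-0.0450 without high humidity replicate 2 to 0.163 without high humidity replicate 3).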

Other observations

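Of 14 clock genes, 10 fell and 2 rose at high against moderate humidity (8 and 2 after median-of-ratios scaling), and the list was not called (camera adjusted p = 0.069; adjusted p = 0.797 with an estimated correlation). RVE1 (AT5G17300) had a log2 fold change of -1.36 (SE 0.13), CDF1 (AT5G62430) of -1.32, PRR9 (AT2G46790) of -0.95 and LNK1 (AT5G64170) of -0.76. TOC1 (AT5G61380) and PIF5 (AT3G59060) rose by 0.47 and 0.30. In the sugar starvation list, DIN10 (AT5G20250) went from 4.12 ± 2.09 to 90.4 ± 45.1 TPM and TPS8 (AT1G70290) rose by 0.95 (2 of 6 risen, camera adjusted p = 0.058; adjusted p = 0.734 with an estimated correlation). The ethylene synthesis gene ACS11 (AT4G08040) went from 0.07 ± 0.115 to 4.72 ± 1.97 TPM. Auxin genes went both ways, with IAA1 (AT4G14560) and IAA5 (AT1G15580) falling by 1.38 and 1.58 and IAA19 (AT3G15540) and IAA6 (AT1G52830) both rising by 1.1. In the cuticle list 4 of 12 genes rose and 5 fell, with WSD1 (AT5G37300), a wax ester synthase gene, at -2.71 (SE 0.28) and LACS2 (AT1G49430) at -1.17.

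Jasmonate genes varied widely between libraries of 1 condition. The mean log2 value of the list ranged from 2.83 to 6.22 at low, 3.62 to 5.51 at moderate and 2.78 to 4.53 at high humidity, and the estimated correlation between its genes was 0.87. Of its 23 genes 2 fell at high against moderate humidity, AOC2 (AT3G25770) and JAR1 (AT2G46370), with adjusted p of 0.044 and 0.047, and both missed the threshold after scaling (adjusted p of 0.069 and 0.111; over their alternatives 0.042 to 0.106 and 0.044 to 0.112).

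Tests of explanations in the next paragraphs were chosen after the result was seen, except the counts of splits that mix all libraries compared. The first pattern is the excess of lower genes at high against moderate humidity, 75.0% of calls. The median log2 fold change was -0.22 here, -0.18 at low against moderate and -0.06 at high against low humidity. In the latter 47.7% of calls were lower. At low against moderate humidity 34.2% of calls were lower, but 388 genes were higher and 5217 lower without low humidity replicate 1. A lower median gene thus went with the moderate libraries and not with high humidity alone. A small number of abundant transcripts taking a larger share is argued against as the whole cause, since after rescaling without the 100 genes of highest mean TPM 66.2% of calls were still lower and the median log2 fold change was -0.15 instead of -0.22. A length or GC trend between libraries stays open, and removing it decides nothing here because each library kept its own mean. Over groups of 1730 genes ordered by length or by GC content the lowest share was 46.9%, in the group of highest GC content, against 70.8 to 80.1% in the other GC groups, and the group of shortest genes had 62.7%, against 68.6 to 84.9% in the other length groups. A real fall of most transcripts per cell cannot be told apart from the scaling, because TPM holds no absolute scale and the 44.9% found after median-of-ratios scaling follows from centring the median gene.

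The second pattern is the rise of touch-inducible and cell wall genes at high humidity. The scaling of the libraries is argued against by the size of the changes over all tested members. Their median log2 fold change was 1.13 for the wall and 0.76 for the touch list as deposited. After median-of-ratios scaling it was 1.28 and 0.96. Under both scalings 10 of 15 wall and 4 of 8 touch genes were called higher, with 5 wall genes lower. Median-of-ratios scaling raised the fold changes of this comparison, so the kept higher calls are no test of the scaling. The 14 members called higher had a median of 2.21 (SD 1.94), the smallest being 0.39, and the scalings differ by 0.21 for the median gene. These members were picked for being higher, so their median decides nothing by itself. One hypothesis is that handling or air movement in the high humidity chamber touched the leaves. Of 10 rapid stress transcription factor genes, which touch also induces for a short time, 1 was called higher, WRKY18 (AT4G31800, adjusted p = 0.023). Adjusted over the list alone 0 rose. Their mean log2 value was 3.75 and 3.64 in high humidity replicates 1 and 4, and 2.30 and 2.48 in replicates 2 and 3, against 2.01 to 3.26 at moderate humidity. With this spread between libraries, few calls do not show that these genes stayed unchanged. Since such transcripts may have returned to their starting level within 1 h and the labels name a chamber for each humidity, this cannot be told apart from a response to humidity.

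Whether other splits of the libraries gave as many calls was counted for each comparison. For high against moderate humidity 1 of 35 splits, the real one, called as many as its 7919 genes, and the highest other split called 1. For high against low humidity 1 of 35 called as many as 4121, with 2 in the highest other split. The real split alone reached these counts, but 1 of 35 is the smallest share that 35 splits can give. Each other split also mixed the 2 conditions, so the splits alone do not exclude chance. For moderate humidity apart from both others 1 of 100 drawn splits called as many as 6353, with 1 in the highest other, and for shared calls 1 of 100 had as many as 86, with 1 in the highest other. These draws mix high humidity libraries into the other groups and so decide nothing about low and moderate humidity. With the high humidity libraries kept in place, a test chosen after the result was seen, 3 of 35 splits of the others called as many as 6353 (highest other 7892) and 2 of 35 shared as many as 86 (highest other 2947), each split taken in the direction with more calls. Both highest counts came from exchanging low humidity replicate 1 with moderate humidity replicate 1, so on the deposited scale chance is not excluded for either and a structure of the samples shows here too. Chance is not excluded for counts of lists called either, where 26 of 35 splits had at least the 6 lists of high against moderate (highest other 16), 14 of 35 at least the 9 of low against moderate (highest other 13) and 8 of 35 at least the 10 of high against low humidity (highest other 16).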
